A study of Homo sapiens with 9 samples.

How the data were processed

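RNA sequencing of the human acute myeloid leukaemia cell line MV4-11, a line that carries an MLL fusion, was analysed in 9 libraries taken at 72 h. Per the labels, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The titles give 3 stems, KO1, NC1 and NCO, with 3 replicates each, and samples were grouped by stem. The characteristics give KO1 as wild type with vehicle, NC1 as wild type with decitabine and NCO as CD36 knockdown with decitabine. A stem that reads as a knockout thus stands on libraries described as untreated wild type. The label of CD36 knockdown stands on NCO, a stem that shares the letters NC with NC1 and does not read as a knockdown. Groups are therefore named by stem, no library was reassigned, and directions are stated between stems. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries.

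The deposited table holds 1 value per gene and library in FPKM, a fragment count normalised for transcript length and library size, as made by the authors. Its header does not name the unit. FPKM was read from the values, which are not whole and whose sums per library differ and lie between 493061 and 530097, and from StringTie, which the submitters' processing notes name and which writes FPKM. The same notes name CASAVA 1.8, Trimmomatic, FastQC, HISAT2 and edgeR and the build GRCh38, without saying what each was used for or in which order. The release of the annotation is not stated, and gene positions are those of the table. Further sheets of the same workbook, with values for part of the genes and with correlations between libraries, were not used here. Read counts were not analysed here, so the depth behind each value is unknown and no counting interval or detection limit is given. Low values were tested for steps that would reveal single reads: the commonest ratio between a pair of libraries of 1 group held for at most 0.367% of low genes, and reads were not recovered.

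Values were analysed as log2(FPKM + 1). Of 60612 genes, 12586 had an FPKM of at least 1 in at least 3 of the 9 libraries and were tested, and 48026 were left out. All 9 libraries were fitted together, with a mean per group, in limma 3.58.1 under R 4.3.3 with a trend and robust empirical Bayes moderation. The comparisons were NC1 minus KO1, NCO minus NC1 and NCO minus KO1. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested. A gene is called higher or lower at an adjusted p under 0.05, and the count that also reached a 2-fold change on this scale is given beside it. Fold changes on this scale understate those of genes with low values, so group means in FPKM with their SD (n = 3) stand beside them, and ratios are ratios of these means. No interaction could be fitted, since no group is labelled as knockdown with vehicle. For CD36 an exact two-sided permutation test of the values was also run. With 3 libraries against 3 its smallest p is 0.1.

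The method was tested on simulated data, in which 50 genes per size of change were altered among 12586. In NC1 minus KO1, 24% of genes changed 1.25-fold were called, 88% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 12 false calls. In NCO minus NC1 the shares were 26%, 86%, 100% and 100%, with 13 false calls. No altered gene was called in the wrong direction. Changes were made on the log2(FPKM + 1) scale, and altered genes with low values were first raised to a minimum level. The shares therefore do not hold for changes in FPKM of genes with low values. Far fewer genes were altered than were called in the data, so the adjusted threshold differs as well.

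Before the data were examined, 24 gene lists were fixed: lipid uptake and transport, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, PPAR and LXR targets, interferon response, germline and cancer-testis genes, immune checkpoint ligands, MHC class I, MHC class II, MyD88 and NF-kB, p53 targets, cell cycle, myeloid differentiation, leukaemia stem cell and MLL targets, DNA methylation and decitabine handling, integrated stress and unfolded protein response, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded genes, markers of erythroid and megakaryocytic, of lymphoid and of stromal or epithelial cells, and heat shock with immediate early genes as a sign of handling. Each list was tested with camera at a preset correlation between genes of 0.01 and with an estimated correlation, adjusted over 72 tests, and with fry. Genes named in the text follow a rule also fixed before: in each comparison CD36, CD274, LYN, MYD88 and DNMT1, then the 10 genes with the largest positive and the 10 with the largest negative fold change among called genes with an official symbol, a group mean of at least 5 FPKM and no overlap between the libraries of the groups, then up to 4 members of each list with the smallest adjusted p. A list member or other gene named outside this rule was chosen after its values were seen, and is marked so. Some genes that the rule names are not reported here.

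Alternatives were no filter on low values, a filter at 5 FPKM, scaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed), quantile normalization, a pseudocount of 0.1, limma without trend and with array weights, a fit of the 6 libraries of a pair alone, the replicate number of the titles as a replicate block, and leaving out each library in turn. Removal of mitochondrial genes was added after the data were seen, with each library rescaled to the same FPKM sum of all other genes. It thus also removes differences in the FPKM sum between groups. Division of the libraries of a group that a pair of comparisons shares, 1 to one and 2 to the other, was added then as well. There a lone library was assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.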

Results

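Gene expression was measured by RNA sequencing in MV4-11 cells, a human acute myeloid leukaemia line, in 3 libraries of each of the title stems KO1, NC1 and NCO. The series concerns CD36, a membrane receptor that takes up fatty acids and oxidised lipoproteins, and resistance to hypomethylating drugs such as decitabine, a cytosine analogue that traps DNA methyltransferases. By their characteristics KO1 is wild type with vehicle, NC1 wild type with decitabine and NCO CD36 knockdown with decitabine, whereas the stem KO1 reads as a knockout. The depth of the libraries is unknown, since values are in FPKM. Sums per library ranged from 493061 to 530097, and between 11885 and 12280 genes reached 1 FPKM. Libraries of 1 group correlated across genes at 0.991 to 0.995, NC1 with NCO at 0.987 to 0.990, and KO1 with either at 0.970 to 0.972. The first principal component held 62.1% of the variance and the second 12.03%. Mitochondrial genes made up 14.9% ± 0.433 (SD, n = 3) of the FPKM sum in KO1, 16.5% ± 1.72 in NC1 and 18.1% ± 0.571 in NCO. NC1 replicate 3, at 14.5%, stood apart from the other NC1 libraries, at 17.6% and 17.3%.

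CD36 (ENSG00000135218, chromosome 7, 80369575 to 80679277, GRCh38) was lowest in the libraries labelled as untreated wild type and was not lower in those labelled as knockdown than in NC1. Its level was 0.126 ± 0.023 FPKM (SD, n = 3) in KO1, 2.18 ± 0.37 in NC1 and 2.49 ± 0.34 in NCO. Per library it was 0.134, 0.144 and 0.0997 in KO1, 2.23, 1.78 and 2.52 in NC1, and 2.31, 2.27 and 2.88 in NCO. NC1 exceeded KO1 by 1.49 on the log2 scale (95% confidence interval 1.24 to 1.74), a ratio of 17.3, with an adjusted p of 1.43e-06 in limma. NCO differed from NC1 by 0.14 (-0.11 to 0.38), with an adjusted p of 0.436. A halving of the NC1 level would be -0.61 on this scale and lies outside that interval. NCO exceeded KO1 by 1.63 (1.38 to 1.87), a ratio of 19.8, with an adjusted p of 8.04e-07. The exact two-sided permutation test gave 0.1, the smallest p that 3 against 3 allows, for both comparisons with KO1, and 0.4 for NCO against NC1. The directions below are therefore those between stems. If the characteristics of KO1 and NCO were exchanged, NC1 minus NCO would be the drug effect and KO1 minus NC1 the knockdown effect.

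**Figure D1:**
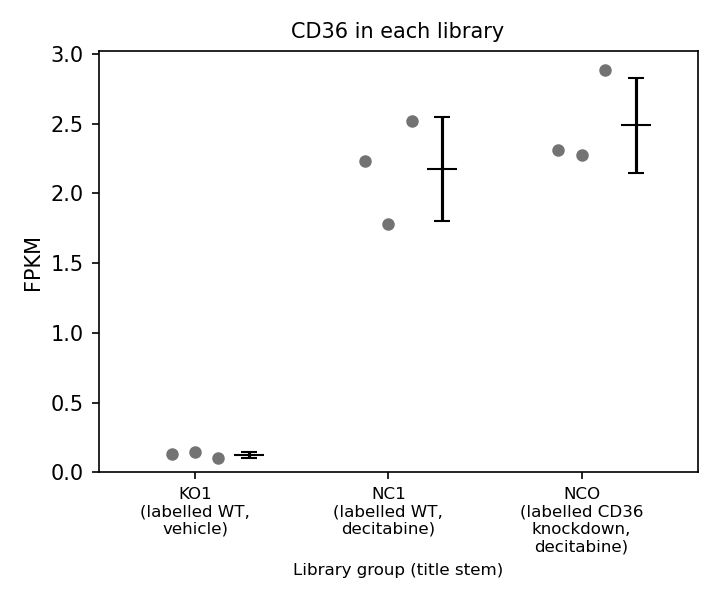
CD36 in each library in FPKM (vertical axis) by title stem with the labelled genotype and treatment (horizontal axis); points are libraries and bars the mean with SD (n = 3). The 3 KO1 libraries lay between 0.0997 and 0.144 FPKM and the 6 others between 1.78 and 2.88.

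NC1 against KO1 is, by the characteristics, the comparison that asks what decitabine changed in wild-type cells. Genes of the antiviral interferon response were far higher in NC1. IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116698), an interferon-induced mitochondrial protein, was at 7.04 ± 0.897 FPKM in KO1 and 396 ± 28.9 in NC1 (SD, n = 3), a ratio of 56.2. The ubiquitin-like modifier ISG15 rose from 40.1 ± 1.04 to 416 ± 28.7, the ISG15 ligase HERC5 from 1.35 ± 0.2 to 42.9 ± 1.77 and IFITM3, which restricts viral entry, from 36.8 ± 4.08 to 655 ± 6.27. Outside these, SEPTIN4, a septin linked to apoptosis, rose from 0.531 ± 0.265 to 40.7 ± 1.53. The homeobox gene OTP fell by 2.58 on the log2 scale, from 5.74 ± 0.34 to 0.128 ± 0.102, the snoRNA host SNHG1 from 132 ± 3.13 to 37.7 ± 3.37 and the steroid-converting reductase AKR1C3 from 199 ± 11.9 to 62.9 ± 3.98.

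Of 34 measured interferon response genes 33 were higher in NC1, 0 lower and 1 not called, and adjusted over the list alone the count was again 33. Their median log2 fold change was 1.8 (camera adjusted p = 6.7e-24; adjusted p = 0.0815 with an estimated correlation). All 11 measured MHC class II genes were higher (median 0.93, adjusted p = 8.39e-08; adjusted p = 0.0625 with an estimated correlation), with HLA-DRA at 4.29 ± 0.33 FPKM in KO1 and 35.7 ± 2.11 in NC1 and the invariant chain CD74 at 294 ± 7.51 and 562 ± 43.7. In the MHC class I list 9 of 16 were higher and 2 lower (median 0.40, adjusted p = 0.0129; adjusted p = 0.327 with an estimated correlation), led by the peptide-loading chaperones PDIA3 (80.3 ± 0.994 and 180 ± 2.9) and CALR (485 ± 14.3 and 1104 ± 13.0). The immune checkpoint list mixes ligands with receptors, enzymes and costimulatory molecules, and 17 of its 22 measured genes were higher and 2 lower. The median of the list was 0.48 (camera adjusted p = 0.000636, or 0.133 with an estimated correlation). NECTIN2 was at 30.8 ± 1.48 and 54.7 ± 3.46 and the inhibitory receptor LILRB4 at 52.8 ± 1.73 and 75.9 ± 1.5. CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470566), lay under the filter and was not tested. Its level was 0.241 ± 0.062 FPKM in KO1, 0.685 ± 0.082 in NC1 and 0.686 ± 0.15 in NCO.

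Heat shock and immediate early genes, in a list that also holds the non-coding RNAs MALAT1 and NEAT1, moved with the interferon genes. In that list 15 of 16 were higher in NC1 and 0 lower (median 1.03, adjusted p = 1.45e-10; adjusted p = 0.0818 with an estimated correlation). The inducible chaperone HSPA1B was at 5.13 ± 0.0738 and 29 ± 1.73 FPKM, HSP90AA1 at 42.1 ± 1.61 and 136 ± 4.55 and the transcription factor JUN at 33.1 ± 1.23 and 90.1 ± 3.24. Myeloid differentiation genes were higher for 16 of 27 and lower for 1 (median 0.38, adjusted p = 0.000425; adjusted p = 0.131 with an estimated correlation), including the lysosomal protein CD68 (72.1 ± 3.33 and 240 ± 15.1). The gene that fell was CEBPA, named after its values were seen. In the MyD88 and NF-kB list 14 of 31 were higher and 1 lower (adjusted p = 0.0519), with the chemokine CCL5 at 294 ± 4.65 and 1280 ± 70.7. The kinase LYN was at 13.9 ± 0.558 and 12.6 ± 0.306 (adjusted p = 0.0821), and was called lower after quantile normalization (adjusted p = 0.0268) and trimmed-mean scaling (adjusted p = 0.01). The adaptor MYD88 was at 8.4 ± 0.605 and 9.8 ± 0.815, an adjusted p of 0.0486 that became 0.183 without KO1 replicate 1 and 0.226 after quantile normalization.

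Among lipid genes, cholesterol synthesis was higher for 14 of 21 and lower for 1 (median 0.40, adjusted p = 0.00862; adjusted p = 0.393 with an estimated correlation). DHCR7, of the last step, was at 15.7 ± 0.854 and 24.7 ± 0.452 FPKM. Adjusted over the list alone, the count for cholesterol synthesis was 16 higher and 3 lower. Lipid uptake and transport genes went both ways, with 10 of 23 higher and 6 lower (adjusted p = 0.625). LPL, the lipase that frees fatty acids from lipoproteins, was at 2.29 ± 0.0987 and 5.6 ± 0.652 and the scaffold protein CAV1 at 1.04 ± 0.159 and 3.53 ± 0.41. Fatty acid synthesis had 6 of 15 higher and 4 lower (adjusted p = 0.88), fatty acid oxidation 5 of 20 higher and 4 lower (adjusted p = 0.722) and PPAR and LXR targets 1 of 11 higher and 4 lower (adjusted p = 0.231). The acyl-CoA dehydrogenase ACADVL rose from 111 ± 4.16 to 214 ± 3.12, while the nuclear receptor PPARG fell from 8.68 ± 1.03 to 5.77 ± 0.538.

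In camera, which compares a list with the other genes, the remaining lists did not pass. The counts were 6 higher and 6 lower of 26 p53 targets, 12 and 12 of 42 cell cycle genes, 5 and 8 of 20 leukaemia stem cell and MLL targets, 4 and 3 of 18 genes of DNA methylation and decitabine handling, 8 and 10 of 22 stress response genes, 7 and 7 of 26 glycolysis and hypoxia genes, 6 and 9 of 26 oxidative phosphorylation genes and 2 and 2 of 15 mitochondrially encoded genes. The balance depended on scaling. Trimmed-mean scaling gave 5 higher and 11 lower p53 targets, 9 and 16 cell cycle genes, 3 and 6 genes of DNA methylation and 3 and 14 oxidative phosphorylation genes. Quantile normalization gave 3 and 12 p53 targets and 2 and 6 genes of DNA methylation, and mitochondrial removal 16 and 11 cell cycle genes and 7 and 6 oxidative phosphorylation genes. Within them the apoptosis inhibitor BCL2 fell from 16.6 ± 0.0621 to 8.14 ± 0.299 FPKM and the oncogene MYC from 37.9 ± 1.37 to 24.9 ± 0.935. The p53 and stress target PMAIP1 rose from 10.6 ± 0.761 to 28.8 ± 2.02, the endoplasmic reticulum chaperone HSPA5 from 98.8 ± 0.788 to 265 ± 12.5, and the nucleoside transporter SLC29A1, which carries cytosine analogues into cells, fell from 70.1 ± 2.11 to 46 ± 0.511. DNMT1, the maintenance DNA methyltransferase, was at 41.2 ± 0.771 and 44.5 ± 1.47 (adjusted p = 0.0693), and was called higher with mitochondrial genes removed (adjusted p = 0.00809). Of 44 germline and cancer-testis genes, often named as responsive to DNA demethylation, 40 lay under the filter. Among the 4 measured, MAGEA4 (11 ± 0.934 and 5.12 ± 0.354) and TKTL1 (42.1 ± 1.1 and 30.1 ± 0.339) were lower and 0 were higher, although MAGEB2 was called higher with mitochondrial genes removed (adjusted p = 0.00754). Markers of other cell types were mostly under the filter. Of those measured, 2 of 3 erythroid and megakaryocytic markers were higher (NFE2 and TFRC, the call of TFRC ending at an adjusted p of 0.0521 without KO1 replicate 2), 2 of 4 lymphoid markers were higher (IL7R, NKG7) and 1 lower (NCAM1), and 3 of 4 stromal or epithelial markers were higher (KRT8, COL1A1, PECAM1). The rotation test fry asks whether the genes of a list move one way on balance and makes no comparison with other genes. Of the lists that did not pass camera, it passed leukaemia stem cell and MLL targets (lower, adjusted p = 0.00166), germline genes (lower, 0.00136), PPAR and LXR targets (lower, 0.0439), lipid uptake and transport (higher, 5.42e-05), MyD88 and NF-kB (higher, 9.28e-05) and erythroid, lymphoid and stromal markers (higher, 0.000224, 0.000181 and 1.35e-05). It also passed fatty acid synthesis (higher, 0.0428), whose median of 0.01 became -0.05 after trimmed-mean scaling and -0.08 after quantile normalization. The median of PPAR and LXR targets went from -0.05 to 0.01 with mitochondrial genes removed, where 2 were higher and 3 lower, so neither direction was settled.

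In the fit across all genes, 5937 of 12586 differed between NC1 and KO1, with 3637 higher and 2300 lower in NC1, and 321 by at least 2-fold, of which 274 were higher and 47 lower. The libraries of the groups did not overlap for 56.5% of genes, against 10% by chance. The share of called genes that were higher, 61.3%, depended on scaling and was 48.8% after trimmed-mean scaling, 47.1% after quantile normalization and 72.2% with mitochondrial genes removed. The median of all genes was 0.06, and mitochondrial removal moved that of NCO minus KO1 from 0.08 to 0.19. That setting also equalises the FPKM sums, which averaged 524669 in KO1, 508628 in NC1 and 494938 in NCO. Its shifts are therefore not due to the mitochondrial share alone. The replicate block gave 5618 genes.

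**Figure D2:**
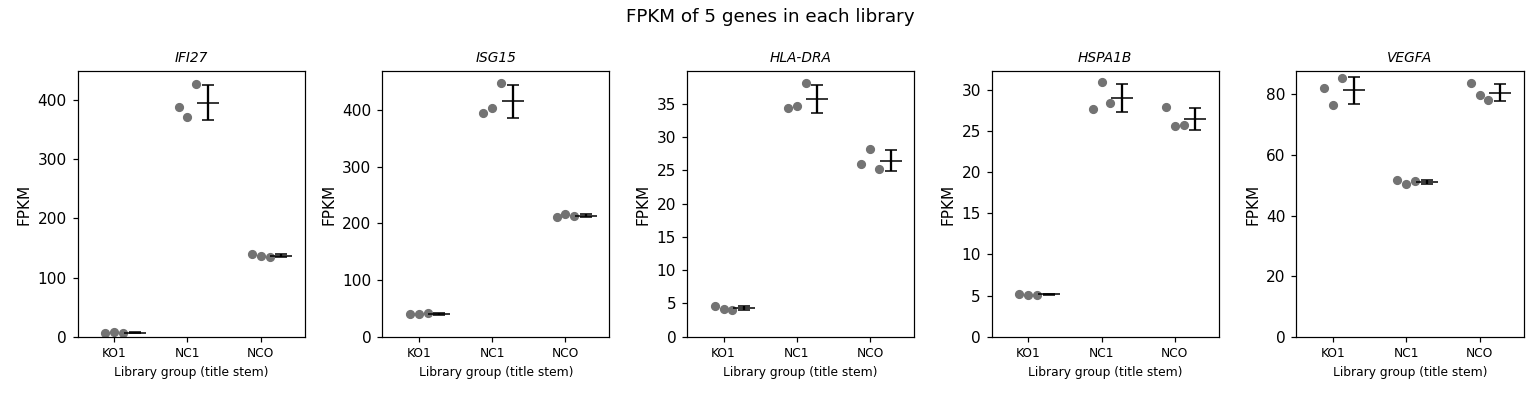
FPKM (vertical axes, starting at 0) of IFI27, ISG15, HLA-DRA, HSPA1B and VEGFA by title stem (horizontal axes); points are libraries and bars the mean with SD (n = 3). IFI27 averaged 7.04, 396 and 137 FPKM in KO1, NC1 and NCO, and VEGFA 81.4, 51.1 and 80.6.

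NCO against NC1 is labelled as CD36 knockdown against wild type, both with decitabine, which asks what CD36 contributes under the drug, although CD36 itself did not differ. Some interferon-induced genes were lower in NCO, among them IFI27, ISG15 and IFITM3, whose means stayed above those of KO1. The size of this fall was not tested against that of the rise from KO1 to NC1. IFI27 fell to 137 ± 2.72 FPKM from 396 ± 28.9 (SD, n = 3; log2 fold change -1.52, SE 0.08, adjusted p = 2.19e-06), ISG15 to 213 ± 2.78 from 416 ± 28.7 and IFITM3 to 330 ± 10.8 from 655 ± 6.27. The secreted glycoprotein LGALS3BP fell to 19.1 ± 1.76 from 45.9 ± 1.07 and the receptor tyrosine kinase AXL to 3.32 ± 0.199 from 8.36 ± 0.229. VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487), an angiogenic growth factor induced by hypoxia, rose to 80.6 ± 2.93 from 51.1 ± 0.761, and the lipid-sensing receptor PPARA to 6.42 ± 0.981 from 3.58 ± 0.276.

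Of the 34 interferon response genes 18 were lower in NCO, 0 higher and 16 not called, with 22 lower when adjusted over the list alone (median -0.32, adjusted p = 1.45e-12; adjusted p = 0.133 with an estimated correlation). HERC5, named here after its values were seen, was at 42.9 ± 1.77 and 42.7 ± 0.975 FPKM and was among those not called. MHC class II genes were lower for 6 of 11 and higher for 0 (median -0.22, adjusted p = 0.000212; adjusted p = 0.0815 with an estimated correlation), with HLA-DRA at 35.7 ± 2.11 and 26.4 ± 1.57 and IFI30, a lysosomal thiol reductase, at 92.6 ± 5.25 and 65.9 ± 0.881. After quantile normalization 3 were lower. MHC class I genes were lower for 9 of 16 and higher for 1 (median -0.21, adjusted p = 0.000336; adjusted p = 0.219 with an estimated correlation), including the immunoproteasome subunits PSMB9 (119 ± 8.79 and 88.6 ± 3.03) and PSMB10 (150 ± 12.2 and 113 ± 3.07). After quantile normalization 8 were lower and 1 higher, with a median of -0.09. In the immune checkpoint list 5 of 22 were lower and 0 higher (adjusted p = 0.0771), with LGALS9, a ligand of TIM-3, at 88.7 ± 3.08 and 63.5 ± 3.6 and NECTIN2 at 54.7 ± 3.46 and 44.7 ± 1.52. In the MyD88 and NF-kB list 6 of 31 were lower and 1 higher (adjusted p = 0.0687), with the chemokine CCL3 at 34 ± 3.71 and 20.9 ± 0.811, while LYN (12.6 ± 0.306 and 13.5 ± 0.627, adjusted p = 0.282) and MYD88 (9.8 ± 0.815 and 9.14 ± 0.389, adjusted p = 0.451) did not pass.

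Among lipid genes, fatty acid synthesis was higher for 6 of 15 and lower for 1 (median 0.16, adjusted p = 0.00256; adjusted p = 0.25 with an estimated correlation). The desaturase SCD was at 72.1 ± 3.12 FPKM in NC1 and 91.8 ± 1.68 in NCO, ACLY, which makes cytosolic acetyl-CoA, at 51.1 ± 0.825 and 60.6 ± 0.546, and the carboxylase ACACA at 7.79 ± 0.632 and 10.3 ± 0.295. The gene that fell, TECR, lost its call without NCO replicate 2 (adjusted p = 0.0592). Cholesterol synthesis had 4 of 21 higher and 2 lower (adjusted p = 0.176), with the epoxidase SQLE at 27.9 ± 1.42 and 34.6 ± 0.251 and the sterol regulator SREBF2 at 58 ± 0.571 and 68.2 ± 2.27. The cholesterol counts became 6 higher and 1 lower after quantile normalization and 7 and 1 with mitochondrial genes removed. Its member LSS lost its call without NCO replicate 1 (adjusted p = 0.0586). Lipid uptake and transport had 3 of 23 higher and 1 lower (adjusted p = 0.826). The acyl-CoA synthetase ACSL5 was at 10.4 ± 0.329 and 12.9 ± 0.567, whereas ACSL4 without NCO replicate 1 (adjusted p = 0.0548), LIPA without NC1 replicate 1 (adjusted p = 0.0674) and MGLL without NC1 replicate 2 (adjusted p = 0.13) lost their calls. Fatty acid oxidation had 2 of 20 higher, PPARA and the carnitine transferase CPT1B (2.48 ± 0.196 and 3.88 ± 0.475; it shares a readthrough transcript with CHKB), and 1 lower, the electron carrier ETFB (109 ± 5.18 and 85 ± 2.28; adjusted p of the list 0.638). Quantile normalization gave 4 fatty acid oxidation genes higher and 1 lower, and mitochondrial removal 5 and 1. PPAR and LXR targets had 1 of 11 higher and 2 lower (adjusted p = 0.301), with the apolipoprotein APOC1 at 11.8 ± 0.814 and 7.14 ± 0.943. The other members called there, MYLIP without NC1 replicate 1 (adjusted p = 0.117) and PLTP without NCO replicate 2 (adjusted p = 0.0938), lost their calls.

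Nuclear oxidative phosphorylation genes were lower for 8 of 26 and higher for 1 (median -0.21, adjusted p = 0.000336; adjusted p = 0.327 with an estimated correlation), with the complex I subunit NDUFA1 at 135 ± 2.73 and 108 ± 4.46 FPKM. After quantile normalization 3 were higher and 2 lower. The mitochondrial share of the FPKM sum overlapped between the groups, at 17.6%, 17.3% and 14.5% in NC1 and 17.4%, 18.2% and 18.5% in NCO, and the lower NC1 mean came mainly from replicate 3. Mitochondrially encoded genes were higher for 2 of 15 and lower for 1 (adjusted p = 0.399), and 0 were called after trimmed-mean scaling. Leukaemia stem cell and MLL targets were higher for 4 of 20 and lower for 0 (median 0.11, adjusted p = 0.00862; adjusted p = 0.275 with an estimated correlation), with the zinc finger repressor ZEB2 at 10.8 ± 1.21 and 17.6 ± 3.05. After quantile normalization 7 were higher and with mitochondrial genes removed 8, with a median of 0.18 in both. The calls of HOXA9 without NCO replicate 1 (adjusted p = 0.112), PBX3 without NC1 replicate 2 (adjusted p = 0.122) and BCL2 without NCO replicate 2 (adjusted p = 0.123) were lost. Myeloid differentiation genes were lower for 9 of 27 and higher for 0 (median -0.06, adjusted p = 0.0244; adjusted p = 0.275 with an estimated correlation), among them the granule proteins AZU1 (1077 ± 40.5 and 842 ± 37.4) and PRTN3 (144 ± 9.07 and 113 ± 6.31). After quantile normalization 2 were higher and 3 lower, and with mitochondrial genes removed 1 was higher and 7 lower, with a median of 0.00. Heat shock and immediate early genes were lower for 4 of 16 and higher for 0 (median -0.08, adjusted p = 0.0252; adjusted p = 0.409 with an estimated correlation), with HSP90AA1 at 136 ± 4.55 and 97.7 ± 1.84 and HSPA1B at 29 ± 1.73 and 26.4 ± 1.33. After quantile normalization 2 of them were higher and 2 lower.

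Glycolysis and hypoxia genes were higher for 4 of 26 and lower for 0 (adjusted p = 0.342), namely VEGFA, HK2, SLC2A1 and ALDOC, with 8 higher after quantile normalization and 7 with mitochondrial genes removed. The glucose transporter SLC2A1 was at 104 ± 3.61 FPKM in KO1, 70.7 ± 2 in NC1 and 82.6 ± 1.88 in NCO. In the DNA methylation and decitabine handling list 3 of 18 were higher and 0 lower (adjusted p = 0.213), with the demethylase TET2 at 1.15 ± 0.052 and 2 ± 0.0733. DNMT1 was at 44.5 ± 1.47 and 50.5 ± 1.39 (adjusted p = 0.0249, which became 0.096 without NCO replicate 2), and DCK lost its call without NCO replicate 1 (adjusted p = 0.0995). The p53 targets had 3 of 26 higher and 4 lower, with the apoptosis effector BAX at 42.6 ± 1.74 and 33.7 ± 0.313, and stress response genes 2 of 22 higher and 3 lower, which became 9 and 2 after quantile normalization and 10 and 2 with mitochondrial genes removed. Of 42 cell cycle genes 1 was higher, MCM4, and 1 lower, CENPF, and both calls were lost without NCO replicate 1 (adjusted p = 0.11 and 0.114). The cell cycle counts became 4 higher and 1 lower after quantile normalization and 7 and 1 with mitochondrial genes removed. In the germline list MAGEA4 fell to 2.23 ± 0.287 from 5.12 ± 0.354 and 0 of 4 were higher. Among markers of other cells, NFE2 was lower (adjusted p = 0.0584 without NC1 replicate 1), as were the lymphoid marker NKG7 (47.9 ± 5.61 and 33.5 ± 1.39) and the epithelial keratin KRT8 (3.14 ± 0.396 and 1.55 ± 0.186). Of the lists that did not pass camera, fry passed checkpoint ligands (lower, adjusted p = 0.00934), MyD88 and NF-kB (lower, 0.035), germline genes (lower, 0.00623), lymphoid and stromal markers (lower, 0.0126 and 0.000215), DNA methylation and decitabine handling (higher, 0.0189) and glycolysis and hypoxia (higher, 0.0315). With mitochondrial genes removed the median of the MyD88 and NF-kB list went from -0.04 to 0.01, with 3 higher and 4 lower, and that of germline genes from -0.06 to 0.01, so these directions depended on scaling.

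Across all genes 1855 differed between NCO and NC1, with 770 higher and 1085 lower in NCO, and 11 by at least 2-fold, of which 1 was higher and 10 lower. The libraries did not overlap for 34.3% of genes, against 10% by chance. The count fell when single libraries were left out, to 908 without NCO replicate 2, 1055 without NCO replicate 1 and 1076 without NC1 replicate 2. It also fell to 1460 without KO1 replicate 1, which is not in this comparison. Fewer libraries lower the power, so these falls do not single out a library. With the replicate block the count was 1389. The share that was higher, 41.5%, was 53.7% after quantile normalization, 52.3% with array weights, 69.8% with mitochondrial genes removed, and 27.8% and 30.3% without NCO replicates 1 and 2.

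NCO against KO1 sets, by the characteristics, knockdown with decitabine against untreated wild type, and by CD36 itself a high group against the low one. SEPTIN4 was at 0.531 ± 0.265 FPKM in KO1 and 44.5 ± 2.08 in NCO (SD, n = 3), a ratio of 83.7, and HERC5 at 1.35 ± 0.2 and 42.7 ± 0.975. IFI27 was at 7.04 ± 0.897 and 137 ± 2.72, and GBP5, an interferon-induced GTPase, at 1.04 ± 0.246 and 14 ± 1.55. Lower in NCO were OTP (5.74 ± 0.34 and 0.117 ± 0.122), AKR1C3 (199 ± 11.9 and 49.3 ± 0.742), the matrix protease MMP9 (16 ± 0.699 and 4.46 ± 0.153) and the leukotriene synthase LTC4S (75.2 ± 0.936 and 25.7 ± 1.66).

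Interferon response genes were higher in NCO than in KO1 for 31 of 34 and lower for 0 (median 1.35, adjusted p = 1.09e-17; adjusted p = 0.0948 with an estimated correlation), and MHC class II genes for 11 of 11 (median 0.72, adjusted p = 3.44e-06; adjusted p = 0.0625 with an estimated correlation). Heat shock and immediate early genes were higher for 15 of 16 (median 1.00, adjusted p = 1.13e-08; adjusted p = 0.0948 with an estimated correlation). Cholesterol synthesis was higher for 13 of 21 and lower for 1 (median 0.40, adjusted p = 0.00158; adjusted p = 0.327 with an estimated correlation), with LSS at 7.54 ± 0.441 and 13.5 ± 0.574 FPKM. In the immune checkpoint list 15 of 22 were higher and 2 lower (median 0.40, adjusted p = 0.012, or 0.25 with an estimated correlation). Myeloid differentiation genes were higher for 15 of 27 and lower for 5 (median 0.37, adjusted p = 0.0129, or 0.25 with an estimated correlation). Of these, the receptor CSF1R was at 14.1 ± 1.19 and 26.6 ± 0.652. Nuclear oxidative phosphorylation genes were lower for 18 of 26 and higher for 3 (median -0.23, adjusted p = 0.000124; adjusted p = 0.306 with an estimated correlation), with NDUFA2 at 149 ± 4.75 and 81.8 ± 2.7 and CYC1 at 236 ± 1.88 and 162 ± 2.1. After quantile normalization 14 were lower and 3 higher (median -0.12), and with mitochondrial genes removed 11 and 4 (median -0.09). The mitochondrial share of the FPKM sum was 14.9% ± 0.433 in KO1 and 18.1% ± 0.571 in NCO, without overlap between their libraries. MHC class I genes were higher for 9 of 16 and lower for 4 (adjusted p = 0.277), and DNMT1 was at 41.2 ± 0.771 and 50.5 ± 1.39 (adjusted p = 0.00035). LYN (adjusted p = 0.634) and MYD88 (adjusted p = 0.244) did not pass, but MYD88 was called higher with mitochondrial genes removed (adjusted p = 0.0224). Without passing camera, fry passed lipid uptake and transport (higher, adjusted p = 3.35e-05), fatty acid synthesis and oxidation (higher, 0.000215 and 0.0265), MHC class I (higher, 6.62e-05), MyD88 and NF-kB (higher, 0.000181), erythroid, lymphoid and stromal markers (higher, 0.00128, 0.00444 and 0.000165), PPAR and LXR targets (lower, 0.00285) and germline genes (lower, 6.62e-05). The lymphoid markers had a median of -0.19 and a mean of 0.31, and the median of fatty acid oxidation went from 0.03 to -0.06 after trimmed-mean scaling, where 5 were higher and 5 lower.

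Across all genes 6568 differed between NCO and KO1, with 4041 higher and 2527 lower in NCO, and 282 by at least 2-fold, of which 217 were higher and 65 lower. Libraries did not overlap for 61.2% of genes, against 10% by chance. The share that was higher, 61.5%, was 48.3% after trimmed-mean scaling, 49.6% after quantile normalization and 78.1% with mitochondrial genes removed. The replicate block gave 6230 genes.

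Whether knockdown undoes drug changes was asked from the genes called in both NC1 minus KO1 and NCO minus NC1. Of these, 794 moved in opposite directions and 316 in the same direction, where independent lists of these sizes would give 454 and 421. IFI27, ISG15 and HLA-DRA were among 538 genes higher in NC1 than in KO1 and lower in NCO than in NC1, and VEGFA and SLC2A1 among 256 that went the other way. Of the 538, 244 were still called higher in NCO than in KO1, 269 were not called and 25 were lower. Most genes higher in NC1 than in KO1, 2850 of 3637, were also higher in NCO than in KO1. These use the same KO1 libraries, whose errors move a gene the same way in both. With the KO1 libraries divided between them, 1 in one and 2 in the other, 1733 to 1946 genes were higher in both over the 6 divisions, against 615 to 703 for independent lists. NC1 minus KO1 and NCO minus NC1 share the NC1 libraries, so an error in NC1 moves a gene in opposite directions. Against simulations without any effect the covariance of the fold changes was more negative (-0.0217 in the data, -0.00765 simulated) and their correlation less so (-0.252 in the data, -0.503 simulated). The simulated correlation is set by the shared NC1 libraries alone. Differences between groups in the data also change the spread of the fold changes, so comparing the correlations decides nothing. With the NC1 libraries divided in the same way, opposite moves numbered 77 to 541, which was 1.47 to 2.81 times the number for independent lists, and moves in the same direction 0.393 to 1.35 times. Opposite moves thus exceeded independent lists in each division, least with NC1 replicate 3 alone against NCO. There, moves in the same direction were also in excess, as in some other divisions. Division removes the error of single libraries, but not a deviation that all NC1 libraries share. It therefore cannot tell a reversal from such a deviation. The count of opposite moves was 439 without NCO replicate 2, 485 without NC1 replicate 2 and 521 without NCO replicate 1, and 614 with the replicate block.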

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

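Removal of mitochondrial genes and division of the NC1 libraries were chosen only after the results were seen. The number of genes called between NC1 and KO1 stayed between 4178 (filter at 5 FPKM) and 6330 (array weights) under the other filters, scalings and fits, and that between NCO and KO1 between 4471 and 7404. Without 1 library they ranged from 4967 to 5978 and from 5626 to 6854. The count for NCO minus NC1, 1855, rose to 2478 with mitochondrial genes removed, 2028 with trimmed-mean scaling, 2014 with array weights and 1995 with quantile normalization, and was 1328 with the pair alone. Without 1 library it ranged from 908 (NCO replicate 2) to 1708 (KO1 replicate 3), with 1055 without NCO replicate 1 and 1076 without NC1 replicate 2, and it fell to 781 with no filter, where 29350 genes shared the adjustment. Genes moved one way and back, 794, were 901 with quantile normalization, 846 with mitochondrial genes removed, 843 with array weights and 835 with trimmed-mean scaling. Without 1 library they ranged from 439 (NCO replicate 2) to 707 (NC1 replicate 3), with 485 without NC1 replicate 2 and 521 without NCO replicate 1, and were 381 with no filter. With the NC1 libraries divided between the comparisons and replicate 1, 2 or 3 alone in NC1 minus KO1 they were 389, 381 and 541, and alone in NCO minus NC1 77, 234 and 419. With a fold change of at least 2 as well, the counts were 321, 11, 282 and 8, by construction lower. With an estimated correlation 0 of 72 list tests passed against 22 with the preset one, and with the replicate block 22. The replicate block gave 5618, 1389 and 6230 genes and 614 back-moves. Libraries of the same number did not resemble each other across groups: their residual correlations were -0.10 to 0.08 over 9 pairs, against -0.07 to 0.11 over 18 others, and 2 of 9 libraries matched their own number best. CD36 kept its direction and side of the threshold in each comparison under every alternative in which it was tested; the filter at 5 FPKM left it out.

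Named genes gave 6010 values over 336 gene comparisons, of which 5712 kept direction and side, 249 lost the call, 25 gained one and 24 changed sign. Those 24 were called under neither setting, and the cause was not tested. With mitochondrial genes removed EPOR was 0.0535 in NC1 minus KO1, MAGEB2 0.0477, EPOR 0.0343 and TFRC 0.0380 in NCO minus NC1, and LYN 0.0938, EPOR 0.0879 and NKG7 0.0710 in NCO minus KO1. In NCO minus NC1 quantile normalization gave 0.0338 for MAGEB2 and 0.0347 for CDC20, and array weights 0.0199 for MAGEB2 and 0.0340 for TFRC. Without 1 library, NC1 minus KO1 ranged from -0.0705 (without KO1 replicate 3) to 0.431 for XAGE1B and from -0.0626 to 0.0237 (without KO1 replicate 1) for EPOR. NCO minus NC1 ranged from -0.0682 (without NC1 replicate 3) to 0.393 for XAGE1B, from -0.0566 to 0.0461 (without NC1 replicate 3) for MAGEB2, from -0.118 to 0.0613 (without NCO replicate 3) for EPOR, from -0.0978 (without NC1 replicate 2) to 0.0759 (without NC1 replicate 3) for TFRC and from -0.0128 (without NCO replicate 2) to 0.127 for NCAM1. NCO minus KO1 ranged from -0.130 to 0.04995 (without NCO replicate 3) for EPOR. No other named value changed sign under the alternatives run. The depth of the libraries is unknown, so what it limits was not assessed.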

Other observations

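The gene families and single genes in this part, and the test on heat shock genes, were chosen only after the results were seen. IFNB1, which encodes interferon beta, was at 0.0469 ± 0.0583 FPKM in KO1, 5.01 ± 1.38 in NC1 and 4.55 ± 0.36 in NCO (SD, n = 3). NC1 exceeded KO1 with a log2 fold change of 2.50 (limma adjusted p = 1.08e-07), and NCO differed from NC1 by -0.09 (adjusted p = 0.683). IFNL1, an interferon lambda gene, was listed at 0 in all KO1 libraries and was at 2.58 ± 0.29 in NC1 and 2.08 ± 0.19 in NCO. CXCL10, a chemokine induced by interferons, was at 1.52 ± 0.0643, 25.3 ± 4.29 and 14.8 ± 0.916.

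Families of genes that share a symbol stem were tested with camera, 129 stems with at least 10 measured members each. A first run had used a minimum of 8, and pseudogenes were left out after a first look, since they share reads with their parent genes. Chromosomes (24) and gene classes (11) were tested as well. In NCO against NC1, 155 of 969 chromosome 19 genes were lower and 18 higher (camera adjusted p = 0.000454, or 0.978 with an estimated correlation). Not all families, chromosomes and classes that passed are reported here. SnoRNA host genes (SNHG) were lower in NC1 than in KO1 for 14 of 24 and higher for 0 (median -0.41, adjusted p = 4.13e-06; adjusted p = 0.986 with an estimated correlation), with SNHG1 at 132 ± 3.13 and 37.7 ± 3.37 FPKM. Ribosomal protein genes were lower for 31 and higher for 6 of 50 RPL genes (median -0.23, adjusted p = 2.25e-06; adjusted p = 0.986 with an estimated correlation) and lower for 26 and higher for 3 of 42 RPS genes (median -0.25, adjusted p = 6.34e-06; adjusted p = 0.986 with an estimated correlation). In NCO against NC1, mitochondrial ribosomal protein genes (MRPL) were lower for 18 of 50 and higher for 0 (median -0.19, adjusted p = 1.47e-06; adjusted p = 0.472 with an estimated correlation). Proteasome beta subunit genes (PSMB) were lower for 8 of 11 (median -0.24, adjusted p = 2.33e-06; adjusted p = 0.145 with an estimated correlation), and so were 7 of 11 complex I genes (NDUFB; median -0.31, adjusted p = 1.35e-05; adjusted p = 0.357 with an estimated correlation). The PSMB stem includes PSMB8, PSMB9 and PSMB10, which are also in the MHC class I list, so these results overlap. Higher in NCO than in NC1, with 0 lower, were 6 of 16 KDM, 4 of 27 TTC and 4 of 43 USP genes. Their adjusted p in camera was 0.000344, 0.0309 and 0.0309, and 0.889 for each with an estimated correlation. The medians of these families in these comparisons kept their sign under trimmed-mean scaling, quantile normalization and mitochondrial removal. Quantile normalization brought that of RPL to -0.12, RPS to -0.16, PSMB to -0.15 and NDUFB to -0.15.

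CD36 was lowest in the libraries labelled as untreated wild type and not reduced in those labelled as knockdown. A candidate explanation is KO1 and NCO labels exchanged. The stem KO1, which reads as a knockout, and the CD36 levels both go with an exchange. A lower CD36 in KO1 than in NC1 could also be the labelled drug effect, so they do not settle it. The planned test on germline genes could not decide, since of the members under the filter 1 reached a group mean of 0.1 FPKM and 5 were needed. In the second test, 10 genes were below 0.1 FPKM in all KO1 libraries and at 1 or more in all NC1 and NCO libraries, among them IFNL1, KCNN1 and IGF2BP1, and 0 showed the converse for NCO. CSAG3, an X-linked cancer-testis gene outside the fixed list, was among the 10. It was at 0 FPKM in KO1, 1.96 ± 0.375 in NC1 and 1.68 ± 0.240 in NCO, the direction that the labelled treatment would give. Of the 4 measured members of the fixed list, 2 were lower and 0 higher in NC1 than in KO1. NCO against KO1 gave the same counts, and with mitochondrial genes removed both gave 1 higher and 2 lower. MAGEA4 was lowest in NCO, as an exchange would give for a gene that the drug raises. Its fall from KO1 to NC1 does not follow from an exchange. So few genes do not decide. Under an exchange KO1 would be the only knockdown group, so genes silent in KO1 alone are allowed by either reading. Genes silent in NCO alone could come from a drug response shared by NC1 and KO1, but the drug need not switch on any gene, so their absence does not tell the readings apart.

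Interferon response genes were higher in NC1 than in KO1. Scaling between libraries as the whole cause was argued against by a lowest median of 1.72 under trimmed-mean scaling and quantile normalization, and a single deviating library by a lowest median of 1.76 without any 1 library. Handling or cell stress that differed between groups stays open for this comparison, since the heat shock list also moved, with a median of 1.03. The labelled decitabine treatment, or the CD36 knockdown if the labels were exchanged, stays among the open explanations, and no design feature separates them.

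Of 34 interferon response genes, 18 were lower in NCO than in NC1, 0 higher and 16 not called. With an estimated correlation the list did not pass (camera adjusted p = 0.133). Under trimmed-mean scaling and quantile normalization the median stayed at -0.31 or below, and with mitochondrial genes removed it was -0.26. Without any 1 library it stayed at -0.27 or below, NC1 replicate 3 included, so neither scaling nor 1 library suffices as the whole cause. The heat shock list moved the same way but little, with 4 of 16 lower, 0 higher and a median of -0.08. After quantile normalization 2 were higher and 2 lower. A rule written after the results were seen excluded stress if the heat shock median lay near 0 and the interferon median did not. It was met, but 4 heat shock genes were lower and 0 higher, so handling or cell stress was not excluded for this comparison. The labelled knockdown was not seen in CD36 mRNA, where NCO differed from NC1 by 0.14 on the log2 scale (95% confidence interval -0.11 to 0.38). The labelled knockdown, or the absence of the drug from NCO if the labels were exchanged, stays among the open explanations. Neither was tested against the interferon genes.

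For the numbers of genes called, 3 libraries against 3 make 10 splits, too few for a share under 0.05. With the 6 libraries of each pair fitted alone, the real split gave 5749 genes for NC1 and KO1 (highest of the other splits 0), 1328 for NC1 and NCO (highest other 2) and 6690 for KO1 and NCO (highest other 1), and in each case 1 of the 10 splits, the real one, gave as many.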
